A study of Mus musculus with 9 samples.

How the data were processed

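RNA came from CD8+ T cells of C57BL/6 mice activated for 3 days with CoA or vehicle, per the labels' protocols. It was extracted with a Qiagen RNeasy kit. From each sample 200 ng was depleted of ribosomal RNA (Ribo-Zero Gold) and made into TruSeq Stranded Total RNA libraries with random primers. The pooled libraries were sequenced as paired ends of 100 cycles on an Illumina HiSeq. Ribosomal depletion keeps RNA without poly(A) tails, such as histone and part of the unspliced RNA, in the counts.

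The authors deposited 1 table of gene counts for the 9 libraries and the same 9 columns as single files, which were identical to the table. The submitters' processing notes name STAR 2.5.2, RSEM 1.3.0 and the builds GRCm38 and mm10 with no role or order; the annotation release, the strand setting and any filter are not given in the sources used here. The deposited counts are whole numbers, while RSEM writes estimated counts that need not be whole, so they may have been rounded before deposit. The kit marks the strand, but since the strand setting of the counting is not known, overlapping and antisense genes may share reads. Reads of near-identical genes (granzymes, chemokines, interferon-inducible GTPases, metallothioneins, class II genes and nuclear copies of mitochondrial genes) may have been split between copies. Of 53679 gene IDs, 53565 carried a symbol; the other 114 held 0.0226% of counts and stayed in the tests. Positions were taken from GENCODE M21 (GRCm38) for 53650 IDs matched by identifier.

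Groups and mice were taken from the sample titles. The design text states that all populations came from each mouse, so mouse was a block in every comparison. As a check, deviations from the group means of libraries from the same mouse correlated with r from 0.0699 to 0.617 (mean 0.360, 9 pairs), and those of different mice and groups from -0.527 to 0.228 (mean -0.180, 18 pairs). Deviations from a group mean cancel out over the libraries of the group. The mean of the pairs of different mice thus follows from that of the same-mouse pairs and adds no separate support. The libraries come from 3 separate animals. With mouse as a block, the p-values rest on how much the differences within a mouse varied from mouse to mouse. They do not rest on the spread of levels between mice.

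Counts were scaled with TMM, filtered with filterByExpr by group (15348 genes tested) and fitted with edgeR 4.0.16's quasi-likelihood F test in R 4.3.3, with group and mouse as terms over all 9 libraries, which left 4 residual degrees of freedom; the biological coefficient of variation was 0.158. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Standard errors of log2 fold changes were approximated as the absolute log2 fold change divided by the square root of F. Values in CPM use the TMM-scaled library sizes. Genes well under 1 CPM rest on few counts per library, and their levels carry counting error besides the spread shown.

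Before the data were examined, 23 gene lists were fixed. Those of T cell programmes were IL-22 and type 17 programme, aryl hydrocarbon receptor targets, STAT3 target genes, cytotoxic and type 1 effector, naive and memory T cell, inhibitory receptor and exhaustion, T cell activation, type 2 cytokine programme and tissue residency. Those of metabolism were coenzyme A synthesis and turnover, glycolysis, pyruvate entry and TCA cycle, nuclear-encoded and mitochondrially encoded oxidative phosphorylation, fatty acid oxidation, fatty acid synthesis and cholesterol synthesis. The others were hypoxia response, integrated stress response and serine synthesis, oxidative stress response, interferon response, cell cycle and ribosome biogenesis. A further 9 lists held markers of cell types: B cell, CD4 and regulatory T cell, macrophage and monocyte, dendritic cell, natural killer cell, gamma delta T cell, granulocyte and mast cell, erythroid cell and CD8 T cell. Members that did not pass the low-count filter were not measured. Lists with at least 3 measured members were tested with limma 3.58.1's camera with a preset correlation of 0.01, two-sided, adjusted over the 31 lists tested in each comparison. With a correlation estimated per list, 0 lists passed in each comparison with Tc0 and 1 in Tc22 against Tc0 with CoA.

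The genes named in the text were chosen by a rule fixed in advance. It takes, per comparison with Tc0, the 8 largest rises and 8 largest falls (5 and 5 for the direct comparison) among genes past the threshold with the same sign in 3 mice, at least 5 CPM on average and a symbol of no predicted model, immunoglobulin or receptor segment. It adds up to 4 members past the threshold per list with the smallest p, or up to 2 where none passes, and a fixed set of cytokine, effector and coenzyme A genes. Some genes that the rule takes were left out. Genes of lists added later were chosen after their values were seen.

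The tests were run on simulated counts of 15142 genes drawn from the real means and library sizes. For Tc22 against Tc0, 26.2%, 69.7% and 90.9% of genes changed 1.5-fold, 2-fold and 4-fold were recovered, with 10 false among 133 calls. For Tc0 with CoA against Tc0 the shares were 25.8%, 57.6% and 90.9%, with 13 false among 128. For Tc22 against Tc0 with CoA they were 29.0%, 72.7% and 90.9%, with 20 false among 274. Changes of 1.5-fold were thus mostly missed in the simulated counts. False calls made up 7.52%, 10.2% and 7.30% of the calls there, above the nominal 5%. The simulation changed 65 or 66 genes per fold in each comparison with Tc0. In the real data 3.68% of the genes tested were called for Tc22 and 24.5% for CoA against Tc0. The adjusted p depends on how many genes change, so these shares need not hold for the real comparisons. For Tc0 with CoA against Tc0, camera recovered 10 of 10 lists of 20 genes raised 1.3-fold with the preset correlation and 4 of 10 with an estimated one, with 0 of 40 unchanged lists called. The simulated genes varied independently of each other. In the real data of that comparison the correlations estimated per list ran from -0.121 (CD4 and regulatory T cell) to 0.663 (ribosome biogenesis). The simulation therefore cannot tell how often the preset correlation gives false calls for correlated lists.

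Alternatives fixed in advance were no mouse block, DESeq2 1.42.0, other scalings (DESeq2's size factors, library size alone, upper quartile), no low-count filter, a filter of 1 CPM in 3 libraries, the compared groups alone, a minimum 2-fold change, an estimated correlation for lists, and leaving out each library and each mouse. DESeq2 gave no adjusted p for 298 genes of Tc22 against Tc0.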

Results

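Total RNA was sequenced from CD8+ T cells of C57BL/6 mice after 3 days of activation in culture. In the field, Tc0 names CD8+ T cells activated without polarising cytokines and Tc22 those that secrete interleukin-22. The culture conditions of either population are not given in the sources used here. Tc0 cells were also activated with coenzyme A (CoA), the carrier of acyl groups that cells build from pantothenate (vitamin B5). Each of the 3 groups held 3 libraries, 1 from each of 3 mice (numbered 715, 725 and 728). Every mouse thus gave a Tc0 library, a Tc0 library with CoA and a Tc22 library.

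Gene counts summed to 31996994, 21841034 and 36254631 in the Tc0 libraries of mice 715, 725 and 728. They summed to 25800950, 27905487 and 22642510 in the Tc0 libraries with CoA and to 28631079, 33739553 and 31931371 in the Tc22 libraries. The Tc0 library of mouse 728 lay farthest from its group. Its counts differed from those of the Tc0 libraries of mice 715 and 725 with a chi-square per degree of freedom of 216 and 127, against 22.3 to 69.8 for the other pairs of replicates. It was also the deepest library. Mitochondrial genes gave 2.003% of its counts (3.97% and 3.33% in the other Tc0 libraries) and histone genes 0.668% (0.140% and 0.188%). Mitochondrial rRNA alone gave 1.18% (2.48% and 1.96%). The mitochondrial share was 3.33%, 2.01% and 2.30% in the Tc22 libraries of mice 715, 725 and 728. Their histone share was 0.252%, 0.408% and 0.493%.

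**Figure D1:**
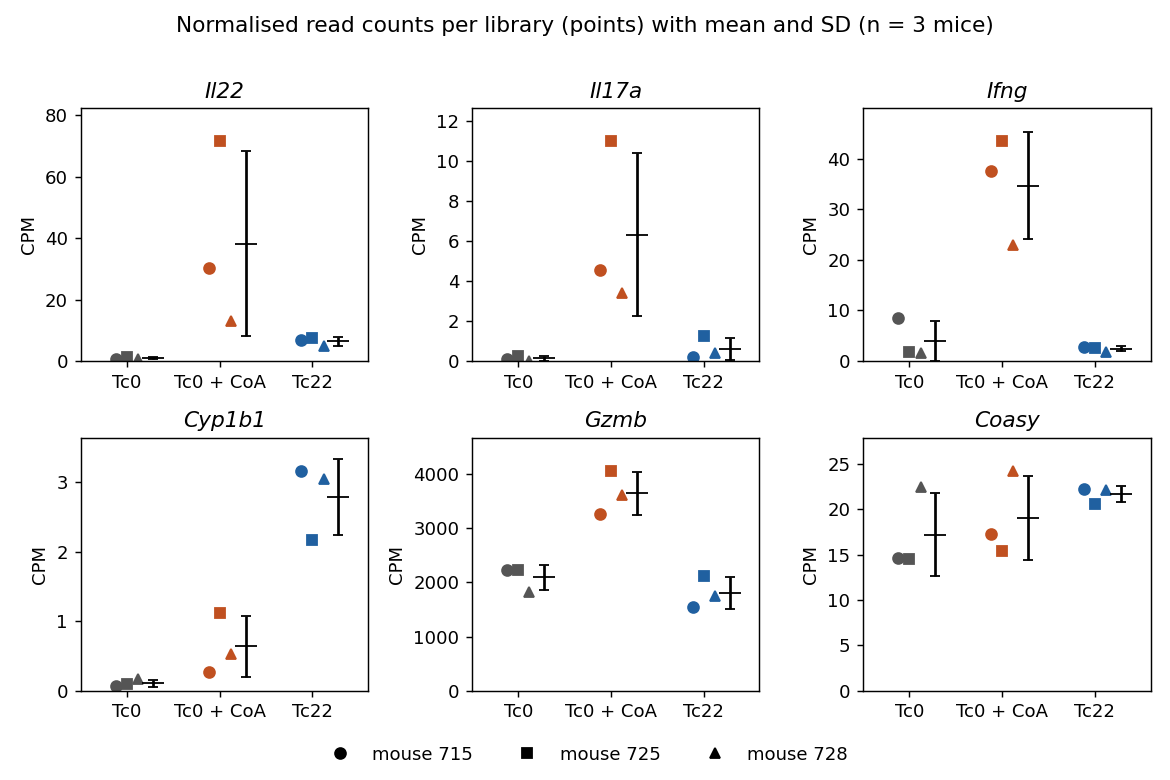
Normalised read counts (CPM, linear axes) of 6 genes in the 9 libraries, with a symbol per mouse and, beside each group, a bar for the mean with its SD (n = 3 mice). Il22 and Il17a were highest in Tc0 cells with CoA, Cyp1b1 was highest in Tc22 cells, and the Coasy values of the groups overlapped.

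The comparison of Tc22 with Tc0 cells asks which transcripts distinguish the interleukin-22 population. Il22 (ENSMUSG00000074695, chromosome 10, 118204942 to 118210047, plus strand, GRCm38) stood at 6.40 ± 1.32 CPM in Tc22 and 0.923 ± 0.375 CPM in Tc0 libraries (mean ± SD, n = 3). It was higher in all 3 mice, with a log2 fold change of 2.87, SE 0.35, adjusted p = 0.00300 by edgeR. Without the mouse block its adjusted p was 0.0728. Il1r1, the interleukin-1 receptor gene, rose (3.98, SE 0.45, adjusted p = 0.00200). Il23r, the interleukin-23 receptor gene, rose too (2.79, SE 0.30, adjusted p = 0.00160), with an adjusted p of 0.138 without the block. Il17a lay near the detection floor, at 0.134 ± 0.131 CPM in Tc0 and 0.611 ± 0.556 CPM in Tc22 libraries (2.19, SE 0.46, adjusted p = 0.0301). That call was lost without the Tc0 library with CoA of mouse 728, the Tc0 libraries of mice 715 or 725 or the Tc22 libraries of mice 725 or 728 (adjusted p from 0.0515 to 0.204). It was lost without the block as well (0.445).

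In the IL-22 and type 17 list, 6 of 18 measured members rose and 2 fell (11 and 2 adjusted over the list alone) in Tc22 cells. Its median log2 fold change was 0.80, with a camera adjusted p of 2.53e-07 (adjusted p = 0.292 with an estimated correlation). Ahr, the gene of the aryl hydrocarbon receptor (ENSMUSG00000019256, chromosome 12, 35497974 to 35535038, minus strand), was among the members that fell, from 9.35 ± 0.850 to 3.74 ± 0.0960 CPM (-1.32, SE 0.16, adjusted p = 0.00308 by edgeR). Targets of that receptor rose: 5 of 10 measured members rose and 0 fell (6 and 0 adjusted over the list alone). The target list had a median of 0.78 and a camera adjusted p of 2.53e-07 (adjusted p = 0.119 with an estimated correlation). Cyp1b1, a cytochrome P450 that the receptor induces (ENSMUSG00000024087, chromosome 17, 79701537 to 79715061, minus strand), went from 0.107 ± 0.0525 to 2.79 ± 0.544 CPM (4.62, SE 0.54, adjusted p = 0.00229). Lpxn, the gene of the adaptor protein leupaxin, went from 103 ± 13.8 to 206 ± 33.9 CPM (0.99, SE 0.10, adjusted p = 0.00119). Cyp1a1, a classic target, rose (3.28, SE 0.56, adjusted p = 0.0114), but its adjusted p was 0.0633 without the Tc0 library of mouse 725. Among STAT3 target genes, 4 of 14 measured members rose and 0 fell (8 and 0 adjusted over the list alone). The STAT3 list had a camera adjusted p of 0.000366 (adjusted p = 0.292 with an estimated correlation).

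Members of the cytotoxic list went both ways. Gzmc and Gzmd, granzyme genes, rose, while Eomes, a transcription factor of effector and memory CD8+ T cells, and Fasl, the gene of Fas ligand, fell. Gzmc (ENSMUSG00000079186, chromosome 14, 56231441 to 56234656, minus strand) went from 1.98 ± 0.796 to 25.4 ± 8.07 CPM (3.64, SE 0.32, adjusted p = 0.000777 by edgeR). Gzmd had a log2 fold change of 4.35, SE 0.53, adjusted p = 0.00287. Gzmc to Gzmf are alike in sequence, so the share of reads given to each is uncertain. Eomes (ENSMUSG00000032446, chromosome 9, 118478212 to 118486132, plus strand) went from 21.3 ± 6.12 to 4.34 ± 1.41 CPM (-2.30, SE 0.14, adjusted p = 0.000119). Fasl had a log2 fold change of -1.99, SE 0.28, adjusted p = 0.00447. Gzmb (-0.22, adjusted p = 0.317), Ifng (-0.50, adjusted p = 0.511), Tnf (-0.03, adjusted p = 0.938) and Il2 (1.19, adjusted p = 0.349) did not pass the threshold.

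In the whole cytotoxic list, 4 of 25 measured members rose and 8 fell (6 and 9 adjusted over the list alone) in Tc22 cells. Its median log2 fold change was -0.30 and its mean -0.01, with a camera adjusted p of 0.0315 (adjusted p = 0.292 with an estimated correlation). This call was lost without the block (adjusted p = 0.415), without the low-count filter (0.0973) and without the Tc0 library of mouse 728 or the Tc22 library of mouse 715, 725 or 728 (0.0831 to 0.114). Of the inhibitory receptor and exhaustion genes, 1 of 17 measured members rose and 4 fell (2 and 7 adjusted over the list alone). That list had a median of -0.48 and a camera adjusted p of 0.000210 (adjusted p = 0.172 with an estimated correlation). Cd38, an NAD-degrading ectoenzyme gene of the list, went from 22.5 ± 1.94 to 7.76 ± 1.83 CPM (-1.53, SE 0.20, adjusted p = 0.00365 by edgeR). Of the T cell activation genes, 5 of 18 measured members rose and 2 fell (5 and 4 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.393). Nfkbia, a feedback inhibitor of NF-kB, rose (1.61, SE 0.18, adjusted p = 0.00200). Of the tissue residency genes, 2 of 13 measured members rose and 0 fell (4 and 0 adjusted over the list alone). The residency list had a camera adjusted p of 0.0155 (adjusted p = 0.296 with an estimated correlation). The residency call was lost without the block (adjusted p = 0.0560), without the low-count filter (0.0726) and without the Tc0 or the Tc22 library of mouse 728 (0.0582 to 0.113).

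Glycolysis and hypoxia response genes shifted upward as lists in Tc22 cells. Of the glycolytic genes, 1 of 22 measured members rose and 0 fell (11 and 0 adjusted over the list alone). The one called over all genes, Hk1 (0.58, SE 0.13, adjusted p = 0.0428 by edgeR), was lost without the Tc0 library with CoA of mouse 728, the Tc0 libraries of mice 715 or 725 or the Tc22 libraries of mice 715 or 725 (adjusted p from 0.0858 to 0.248). Hk1 was also lost without the block (0.511), with the compared groups alone (0.0598) and with library size alone as the scaling. Their median log2 fold change was 0.37, or 0.58 without the Tc22 library of mouse 728, with a camera adjusted p of 5.71e-05 (adjusted p = 0.547 with an estimated correlation). Of the hypoxia response genes, 2 of 23 measured members rose and 0 fell (9 and 0 adjusted over the list alone). Of those called over all genes, Mxi1 (0.48, SE 0.10, adjusted p = 0.0333) was lost without the Tc0 library with CoA of mouse 728, the Tc0 libraries of mice 715 or 725 or any Tc22 library (adjusted p from 0.0674 to 0.170). Without the block Mxi1 stood at 0.467 and Bhlhe40 (0.91, SE 0.13, adjusted p = 0.00591) at 0.0633. The hypoxia median was 0.37, or 0.55 without the Tc0 library of mouse 725, with a camera adjusted p of 5.71e-05 (adjusted p = 0.547 with an estimated correlation). Among the Tc0 libraries both lists were highest in that of mouse 728.

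Of the respiratory chain genes encoded in the mitochondrial genome, 0 of 13 measured members rose and 1 fell (0 and 1 adjusted over the list alone) in Tc22 cells. The one called, mt-Nd4l (-1.65, SE 0.29, adjusted p = 0.0138 by edgeR), was lost without the Tc0 library of mouse 715 (adjusted p = 0.0505) and without the block (0.139). Their median was -0.31, or -0.18 without the Tc0 library of mouse 715 and -0.47 without that of mouse 728, with a camera adjusted p of 0.00111 (adjusted p = 0.547 with an estimated correlation). Mitochondrial genes gave 2.54% ± 0.694 of all counts in Tc22 and 3.10% ± 1.001 in Tc0 libraries (SD, n = 3). This share includes mitochondrial rRNA, at 1.52% ± 0.625 in Tc22 and 1.87% ± 0.653 in Tc0 libraries, which the list leaves out. In the oxidative stress list, 4 of 18 measured members rose and 0 fell (6 and 0 adjusted over the list alone). That list had a camera adjusted p of 0.0127 (adjusted p = 0.303 with an estimated correlation). Its call was lost without the block (adjusted p = 0.0924), without the low-count filter (0.0520) and without the Tc0 library of mouse 728 (0.116). Fth1, the heavy chain of ferritin, went from 215 ± 9.78 to 368 ± 18.3 CPM (0.77, SE 0.10, adjusted p = 0.00433 by edgeR).

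Other large rises in Tc22 cells at 5 CPM or more were those of Ermn (3.31, SE 0.19, adjusted p = 9.24e-05 by edgeR), which encodes the cytoskeletal protein ermin, and Ltb4r1 (2.95, SE 0.20, adjusted p = 0.000144), the gene of a leukotriene B4 receptor. Iigp1, an interferon-inducible GTPase of cell-autonomous defence (ENSMUSG00000054072, chromosome 18, 60376027 to 60392634, plus strand), had the largest fall. It went from 49.4 ± 39.2 to 0.959 ± 0.344 CPM (-5.43, SE 0.53, adjusted p = 0.000973).

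The lists of B cell and natural killer cell markers passed by camera in Tc22 against Tc0, in the upward direction. Of the B cell markers, 2 of 6 measured members rose and 0 fell (4 and 0 adjusted over the list alone). The B cell list had a camera adjusted p of 0.00299 (adjusted p = 0.296 with an estimated correlation) and was lost without the low-count filter (adjusted p = 0.368). Summed over the list, B cell markers stood at 258.4 ± 126.9 CPM in Tc22 and 309.2 ± 141.7 CPM in Tc0 libraries (SD, n = 3). Cd74, the invariant chain of MHC class II, went from 4.08 ± 0.766 to 13.9 ± 3.18 CPM (1.74, SE 0.22, adjusted p = 0.00309 by edgeR). The other called member, H2-Ab1 (1.09, SE 0.20, adjusted p = 0.0172), was lost without the Tc0 or Tc22 libraries of mice 715 or 725 (adjusted p from 0.0517 to 0.116) and without the block (0.593). Of the natural killer cell markers, 1 of 5 measured members rose and 0 fell (3 and 0 adjusted over the list alone). The one called over all genes, Klra7 (1.78, SE 0.40, adjusted p = 0.0428), was lost without the Tc0 library with CoA of mouse 728, the Tc0 libraries of mice 725 or 728 or any Tc22 library (adjusted p from 0.0510 to 0.214) and without the block (0.245). Their list had a camera adjusted p of 0.0122 (adjusted p = 0.292 with an estimated correlation), and was lost without the Tc0 or the Tc22 library of mouse 728 (adjusted p from 0.0781 to 0.0959). They summed to 36.3 ± 10.7 CPM in Tc22 and 19.3 ± 10.1 CPM in Tc0 libraries. By camera the markers of CD4 and regulatory T cells (2 higher and 0 lower of 7, adjusted p = 0.289) and gamma delta T cells (1 higher and 0 lower of 5, adjusted p = 0.861) did not pass. EdgeR called 0 of 6 macrophage and monocyte markers (3 at an unadjusted p under 0.05, 0 by DESeq2, camera adjusted p = 0.718) and 0 of 6 dendritic cell markers (1, 0 and 0.464). It called 0 of 3 granulocyte and mast cell markers (1, 0 and 0.871) and 0 of 12 CD8 T cell markers (3, 0 and 0.871). Of the erythroid list 1 member was measured, and the list was not tested.

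Coenzyme A genes did not pass in Tc22 against Tc0. In the coenzyme A synthesis and turnover list edgeR called 0 of 17 measured members (3 at an unadjusted p under 0.05, 0 by DESeq2, camera adjusted p = 0.393). Coasy, whose product makes CoA from phosphopantetheine (ENSMUSG00000001755, chromosome 11, 101082565 to 101086619, plus strand), had 21.7 ± 0.897 CPM in Tc22 and 17.2 ± 4.60 CPM in Tc0 libraries (0.37, SE 0.15, adjusted p = 0.205). By camera, the lists for naive and memory T cells (1 higher and 2 lower of 19, adjusted p = 0.861), type 2 cytokines (2 higher and 0 lower of 10, adjusted p = 0.326) and pyruvate entry and the TCA cycle (1 higher and 0 lower of 26, adjusted p = 0.861) did not pass. Camera's direction for the TCA list was lower, against a median and a mean of 0.01. Fatty acid oxidation (1 higher and 0 lower of 24, adjusted p = 0.340) and the interferon response (1 higher and 1 lower of 23, adjusted p = 0.393) did not pass either. EdgeR called 0 of 57 genes of nuclear-encoded oxidative phosphorylation (9 at an unadjusted p under 0.05, 2 by DESeq2, camera adjusted p = 0.464). It called 0 of 18 genes of fatty acid synthesis (5, 1 and 0.254) and 0 of 25 of cholesterol synthesis (5, 1 and 0.210). It called 0 of 23 integrated stress response and serine synthesis genes (2, 2 and 0.272), 0 of 30 cell cycle genes (4, 0 and 0.464) and 0 of 25 ribosome biogenesis genes (3, 0 and 0.464).

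In all, 380 genes were higher and 185 lower in Tc22 than in Tc0 cells of 15348 tested by edgeR, and 564 of the 565 moved the same way in all 3 mice. Without the mouse block the counts were 87 and 33, by DESeq2 621 and 332, and without the low-count filter 831 and 444. Single libraries moved them: they were 1555 and 1114 without the Tc0 library of mouse 728, 148 and 59 without that of mouse 725 and 178 and 107 without that of mouse 715. They were 165 and 77 without the Tc22 library of mouse 715 and 148 and 53 without that of mouse 725, and 123 genes were lower without the Tc0 library with CoA of mouse 728.

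The comparison of Tc0 cells with and without CoA asks what the cofactor, added during activation, does to transcript levels. Transcripts of Il22, Il17a, Ifng, Il2 and Ccl4 were higher with CoA. Il22 rose from 0.923 ± 0.375 to 38.2 ± 30.1 CPM (mean ± SD, n = 3), a log2 fold change of 5.18, SE 0.36, adjusted p = 0.000162 by edgeR. Il17a (ENSMUSG00000025929, chromosome 1, 20730905 to 20734496, plus strand) rose from 0.134 ± 0.131 to 6.32 ± 4.09 CPM (5.65, SE 0.38, adjusted p = 0.000153), and both were higher in all 3 mice. Ifng, the gene of interferon gamma (ENSMUSG00000055170, chromosome 10, 118441046 to 118445892, plus strand), went from 3.99 ± 3.99 to 34.6 ± 10.6 CPM (3.34, SE 0.41, adjusted p = 0.00181). Il2, a T cell growth factor gene, went from 0.140 ± 0.112 to 7.09 ± 6.91 CPM (5.37, SE 0.55, adjusted p = 0.000773). Ccl4, a chemokine gene, went from 0.763 ± 0.111 to 10.5 ± 5.04 CPM (3.67, SE 0.31, adjusted p = 0.000382). Ccl3 and Ccl4 are alike in sequence, so the share of reads given to each is uncertain.

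Of the IL-22 and type 17 genes, 12 of 18 measured members rose and 1 fell (14 and 1 adjusted over the list alone) with CoA. The list had a median log2 fold change of 0.77 and a camera adjusted p of 1.69e-12 (adjusted p = 0.232 with an estimated correlation). Il1r1 (4.23, SE 0.45, adjusted p = 0.000916 by edgeR) and Il23r (3.90, SE 0.30, adjusted p = 0.000329) rose. Ahr rose (0.52, SE 0.16, adjusted p = 0.0381), but its call was lost without the Tc0 libraries with CoA of mice 725 or 728, the Tc0 libraries of mice 715, 725 or 728 or the Tc22 libraries of mice 715 or 725 (adjusted p from 0.0524 to 0.217). The Ahr call was also lost without the block (0.0907), without the low-count filter (0.0640) and with the compared groups alone (0.0757). Aryl hydrocarbon receptor targets went both ways: 3 of 10 measured members rose and 4 fell (4 and 4 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.949). Scin, the gene of an actin-severing protein, rose (3.73, SE 0.48, adjusted p = 0.00218). Nqo1, a quinone reductase gene, fell from 6.52 ± 0.221 to 1.34 ± 0.529 CPM (-2.32, SE 0.23, adjusted p = 0.000704). Of the STAT3 target genes, 4 of 14 measured members rose and 1 fell (4 and 1 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.315).

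Cytotoxic and type 1 effector genes rose as a list with CoA: 15 of 25 measured members rose and 2 fell (16 and 3 adjusted over the list alone). The list had a median log2 fold change of 0.70 and a camera adjusted p of 1.03e-09 (adjusted p = 0.0609 with an estimated correlation). Gzmb, the gene of granzyme B, went from 2094 ± 234 to 3648 ± 402 CPM (0.80, SE 0.12, adjusted p = 0.00353 by edgeR). Gzmc rose (3.09, SE 0.32, adjusted p = 0.000822). Tnf rose (0.70, SE 0.16, adjusted p = 0.0140), but not past the threshold without the Tc0 libraries with CoA of mice 725 or 728 or the Tc0 library of mouse 725 (adjusted p from 0.0544 to 0.0749). In the type 2 cytokine list, 7 of 10 measured members rose and 1 fell (7 and 1 adjusted over the list alone). Its members Il4, Il5, Il9 and Areg did not pass the low-count filter and were not measured. That list had a median of 1.58 and a camera adjusted p of 5.19e-06 (adjusted p = 0.102 with an estimated correlation). Il13 stood at 6.56 ± 2.35 CPM with CoA and 0.0105 ± 0.0182 CPM without. Il3 stood at 1.603 ± 1.41 CPM with CoA and 0.0365 ± 0.0327 CPM without. Too few counts lay in the Tc0 libraries for a fold of either. Csf2, the gene of the growth factor GM-CSF, went from 0.554 ± 0.219 to 5.33 ± 3.38 CPM (3.18, SE 0.34, adjusted p = 0.000967). In the same libraries markers of granulocytes and mast cells were higher as a list (median 2.77; camera adjusted p = 0.00132, and adjusted p = 0.277 with an estimated correlation).

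Genes induced by T cell receptor signals rose in part with CoA. Of the T cell activation list, 6 of 18 measured members rose and 2 fell (7 and 2 adjusted over the list alone). The activation list had a camera adjusted p of 0.0341 (adjusted p = 0.461 with an estimated correlation). It was lost without the block (adjusted p = 0.0924) and without the Tc0 library with CoA of mouse 725 or the Tc0 libraries of mice 725 or 728 (0.0674 to 0.0855). Egr2, an early growth response factor gene (1.64, SE 0.21, adjusted p = 0.00195 by edgeR), and Tfrc, the transferrin receptor gene (1.04, SE 0.14, adjusted p = 0.00263), rose. Dusp6, the gene of an ERK phosphatase, fell (-1.24, SE 0.16, adjusted p = 0.00199). Of the naive and memory T cell list, 2 of 19 measured members rose and 6 fell (3 and 8 adjusted over the list alone). The naive and memory list had a camera adjusted p of 0.0341 (adjusted p = 0.614 with an estimated correlation). It was lost without the block (adjusted p = 0.0945) and without the Tc0 libraries, with or without CoA, of mice 725 or 728 (0.0589 to 0.0972). Id3 fell (-1.30, SE 0.22, adjusted p = 0.00456) and Satb1 rose (0.70, SE 0.12, adjusted p = 0.00542), while Tcf7 did not pass (-0.46, SE 0.17, adjusted p = 0.0792).

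Of the inhibitory receptor and exhaustion genes, 3 of 17 measured members rose and 6 fell (4 and 6 adjusted over the list alone) with CoA, and the list did not pass (camera adjusted p = 0.807). Nr4a1 rose (1.74, SE 0.23, adjusted p = 0.00218 by edgeR) and Tox fell (-0.95, SE 0.15, adjusted p = 0.00368). The tissue residency list did not pass either, with 2 higher and 2 lower of 13 (adjusted p = 0.324). Prdm1, the gene of the transcription factor Blimp-1, fell (-2.64, SE 0.37, adjusted p = 0.00266).

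**Figure D2:**
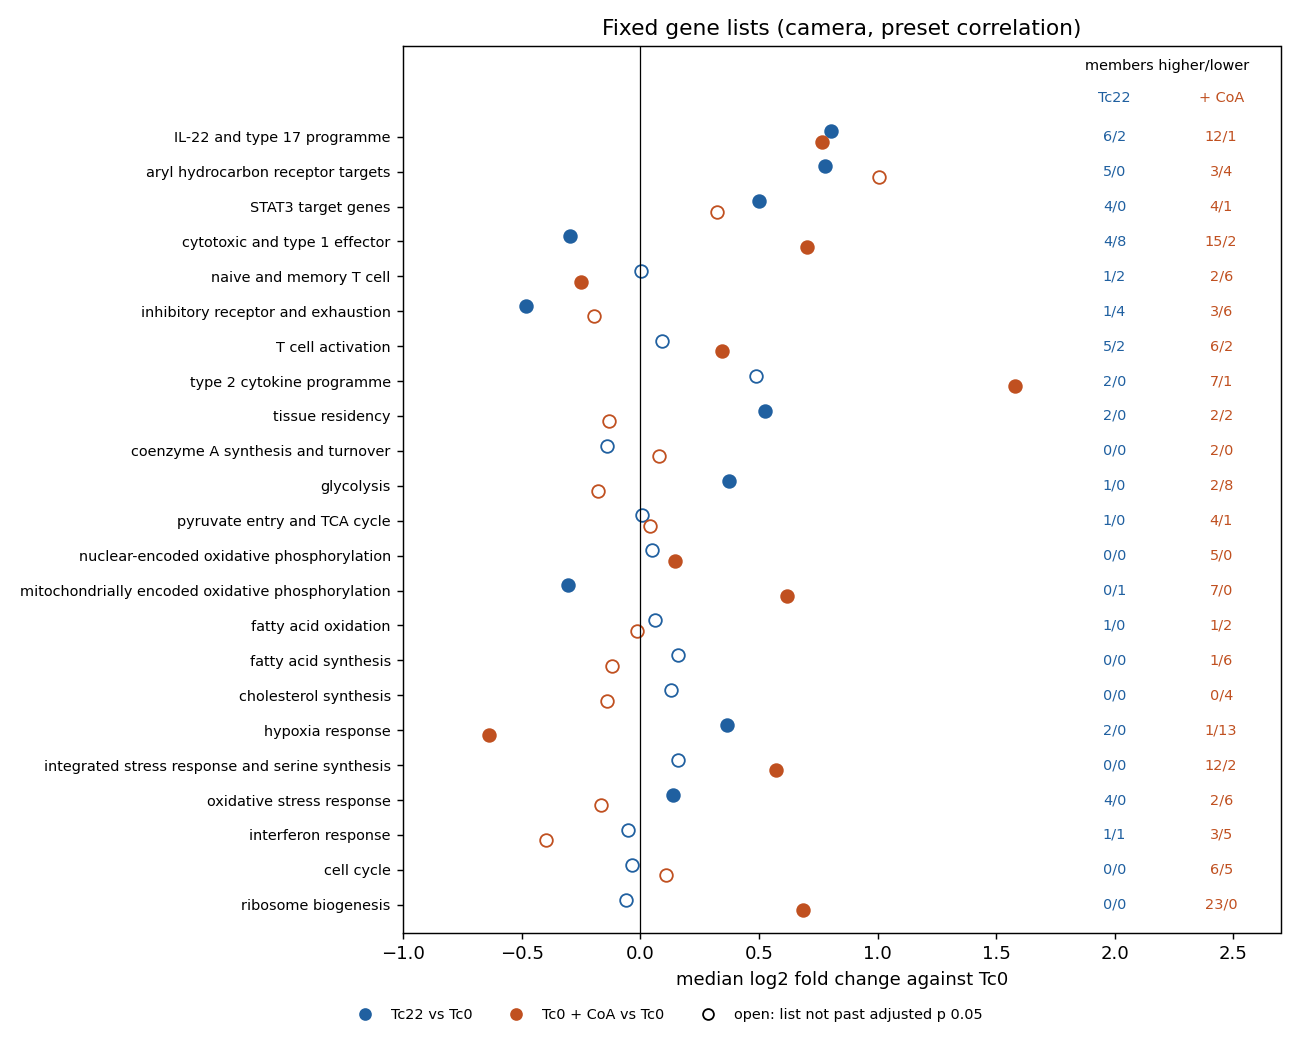
Median log2 fold change against Tc0 (horizontal axis) of the 23 fixed gene lists in Tc22 cells and in Tc0 cells with CoA, where filled points passed camera's test with a preset correlation at an adjusted p of 0.05 and printed numbers are members higher and lower. With CoA, ribosome biogenesis had 23 members higher and 0 lower, and the hypoxia response had 13 lower and 1 higher.

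Genes of ribosome production rose with CoA and hypoxia response genes fell. Of the ribosome biogenesis list, 23 of 25 measured members rose and 0 fell (24 and 0 adjusted over the list alone). Its median log2 fold change was 0.68, with a camera adjusted p of 7.65e-16 (adjusted p = 0.454 with an estimated correlation). Nolc1 (1.11, SE 0.15, adjusted p = 0.00263 by edgeR) and Nop56 (0.95, SE 0.14, adjusted p = 0.00305), which encode nucleolar proteins, rose. Of the hypoxia response list, 1 of 23 measured members rose and 13 fell (1 and 13 adjusted over the list alone). The hypoxia median was -0.64, or -0.37 without the Tc0 library with CoA of mouse 725, with a camera adjusted p of 1.65e-05 (adjusted p = 0.493 with an estimated correlation). Bnip3l, a mitophagy receptor gene (-1.24, SE 0.21, adjusted p = 0.00514), and P4ha1, a collagen prolyl hydroxylase gene (-0.78, SE 0.13, adjusted p = 0.00431), fell. Of the glycolytic genes, 2 of 22 measured members rose and 8 fell (3 and 8 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.152). Pgk1, the gene of phosphoglycerate kinase, fell (-0.71, SE 0.13, adjusted p = 0.00590).

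**Figure D3:**
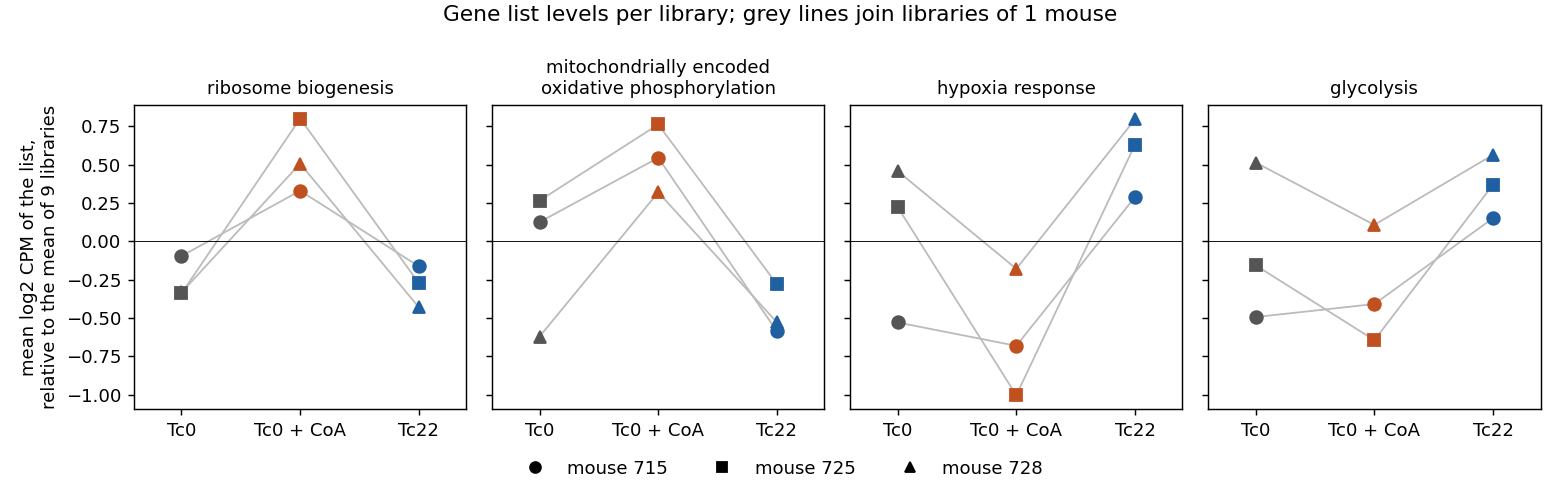
Mean log2 CPM of 4 lists in each library, relative to the mean over the 9 libraries (vertical axis), with grey lines joining the libraries of a mouse. With CoA the ribosome biogenesis and mitochondrially encoded lists lay above, and the hypoxia list below, the Tc0 library of the same mouse in all 3 mice, while glycolysis lay above it in mouse 715 and below it in mice 725 and 728.

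Mitochondrially encoded transcripts were higher with CoA. Of these respiratory genes, 7 of 13 measured members rose and 0 fell (10 and 0 adjusted over the list alone). Their median was 0.62, with a camera adjusted p of 1.52e-05 (adjusted p = 0.461 with an estimated correlation). The gene mt-Cytb, a complex III subunit, went from 408 ± 109.6 to 782 ± 140.0 CPM (0.96, SE 0.13, adjusted p = 0.00237 by edgeR). Nuclear copies of mitochondrial genes make the reads given to each uncertain. Mitochondrial genes gave 3.43% ± 0.692 of all counts with CoA and 3.10% ± 1.001 without (SD, n = 3), and were lowest among the Tc0 libraries in that of mouse 728. This share includes mitochondrial rRNA, which the list leaves out. Mitochondrial rRNA gave 1.76% ± 0.400 of all counts with CoA and 1.87% ± 0.653 without. Of the nuclear-encoded respiratory genes, 5 of 57 measured members rose and 0 fell (2 and 0 adjusted over the list alone). The nuclear-encoded list had a median of 0.15 and a camera adjusted p of 0.0131 (adjusted p = 0.596 with an estimated correlation). It was lost without the Tc0 library with CoA of mouse 728 (adjusted p = 0.0572).

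Of the integrated stress response and serine synthesis genes, 12 of 23 measured members rose and 2 fell (14 and 3 adjusted over the list alone) with CoA. Their median was 0.57, with a camera adjusted p of 0.000283 (adjusted p = 0.493 with an estimated correlation). Slc7a11, the cystine transporter gene (2.17, SE 0.22, adjusted p = 0.000716 by edgeR), Atf3, a stress-induced transcription factor gene (1.91, SE 0.25, adjusted p = 0.00224), and Psph, the last enzyme of serine synthesis (0.84, SE 0.14, adjusted p = 0.00467), rose.

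In the coenzyme A synthesis and turnover list, 2 of 17 measured members rose and 0 fell (0 and 0 adjusted over the list alone) with CoA, and the list did not pass (camera adjusted p = 0.687). The members past the threshold over all genes were Slc5a6, the pantothenate transporter gene (ENSMUSG00000006641, chromosome 5, 31036036 to 31048924, minus strand), and Nudt19, which encodes a CoA diphosphatase. Slc5a6 (0.58, SE 0.18, adjusted p = 0.0444 by edgeR) was lost without the Tc0 libraries with CoA of mice 725 or 728, the Tc0 libraries of mice 715 or 725 or the Tc22 libraries of mice 715 or 725 (adjusted p from 0.0598 to 0.234). Nudt19 (0.43, SE 0.11, adjusted p = 0.0233) was lost without the Tc0 libraries with CoA of mice 725 or 728 or the Tc0 library of mouse 725 (adjusted p from 0.109 to 0.142). Without the block they stood at 0.0827 and 0.158, and with the compared groups alone at 0.0710 and 0.0593. Without the low-count filter Slc5a6 stood at 0.0538. The pantothenate kinase genes Pank1 (0.20, adjusted p = 0.377), Pank2 (-0.05, adjusted p = 0.714), Pank3 (-0.31, adjusted p = 0.0791) and Pank4 (-0.12, adjusted p = 0.534) did not pass. Ppcs (-0.05, adjusted p = 0.850), Ppcdc (0.30, adjusted p = 0.186) and Coasy (0.15, adjusted p = 0.516), the genes of the later steps of CoA synthesis, did not pass either.

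The remaining metabolic and stress lists did not pass by camera with CoA. Pyruvate entry and the TCA cycle had 4 higher and 1 lower of 26 (adjusted p = 0.315), fatty acid oxidation 1 higher and 2 lower of 24 (adjusted p = 0.646) and fatty acid synthesis 1 higher and 6 lower of 18 (adjusted p = 0.152). Cholesterol synthesis had 0 higher and 4 lower of 25 (adjusted p = 0.324) and the oxidative stress response 2 higher and 6 lower of 18 (adjusted p = 0.0692). The interferon response had 3 higher and 5 lower of 23 (adjusted p = 0.152) and the cell cycle 6 higher and 5 lower of 30 (adjusted p = 0.774). Cpt1a, the enzyme that admits fatty acids to mitochondria, fell (-0.95, SE 0.13, adjusted p = 0.00248 by edgeR), and Ccne1, the gene of cyclin E1, rose (0.64, SE 0.10, adjusted p = 0.00417).

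Among the largest rises with CoA at 5 CPM or more was that of Penk, the gene of preproenkephalin (ENSMUSG00000045573, chromosome 4, 4133531 to 4138819, minus strand), from 1.25 ± 0.912 to 49.9 ± 19.3 CPM (5.45, SE 0.32, adjusted p = 7.33e-05 by edgeR). Lmna, the gene of lamin A and C, rose (4.88, SE 0.41, adjusted p = 0.000382), and so did Upp1, the gene of uridine phosphorylase (4.81, SE 0.23, adjusted p = 3.01e-05). Cd7 (ENSMUSG00000025163, chromosome 11, 121036747 to 121039418, minus strand) had the largest fall (-4.64, SE 0.53, adjusted p = 0.00125, and adjusted p = 0.0504 without the block). Klhl24 (-2.89, SE 0.32, adjusted p = 0.00118) and Frat2 (-2.73, SE 0.24, adjusted p = 0.000456) fell too.

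Markers of dendritic cells and of granulocytes and mast cells were higher with CoA, and CD8 T cell markers lower. Of the dendritic cell markers, 3 of 6 measured members rose and 0 fell (3 and 0 adjusted over the list alone). Their median was 0.89, or 0.57 without the Tc0 library with CoA of mouse 725 and 3.08 with the filter of 1 CPM in 3 libraries, with a camera adjusted p of 0.000867 (adjusted p = 0.454 with an estimated correlation). The chemokine gene Ccl22 went from 3.75 ± 1.81 to 32.1 ± 15.1 CPM (3.07, SE 0.28, adjusted p = 0.000551 by edgeR), and the list summed to 43.5 ± 18.7 CPM with CoA and 8.27 ± 2.68 CPM without. Of the granulocyte and mast cell markers, 2 of 3 measured members rose and 0 fell (3 and 0 adjusted over the list alone). That list had a median of 2.77 and a camera adjusted p of 0.00132 (adjusted p = 0.277 with an estimated correlation), and summed to 3.82 ± 1.76 CPM with CoA and 0.730 ± 0.479 CPM without. Mcpt8, a basophil protease gene, rose (2.77, SE 0.45, adjusted p = 0.00431). Of the CD8 T cell markers, 0 of 12 measured members rose and 5 fell (0 and 5 adjusted over the list alone). Their median was -0.24, or -0.15 without the Tc0 library with CoA of mouse 725, with a camera adjusted p of 0.0287 (adjusted p = 0.634 with an estimated correlation). The CD8 call was lost without the Tc0 libraries with CoA of mice 725 or 728 or the Tc0 library of mouse 728 (adjusted p from 0.0572 to 0.110). Cd3d, a T cell receptor complex gene, fell (-0.79, SE 0.14, adjusted p = 0.00616).

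The other marker lists did not pass by camera with CoA. B cell markers had 3 higher and 1 lower of 6 (adjusted p = 0.0791), CD4 and regulatory T cell markers 2 higher and 0 lower of 7 (adjusted p = 0.250), and macrophage and monocyte markers 2 higher and 0 lower of 6 (adjusted p = 0.0531). Natural killer cell markers had 1 higher and 1 lower of 5 (adjusted p = 0.848), with a median of 0.20, a mean of -0.20 and camera's direction higher. Gamma delta T cell markers had 0 higher and 1 lower of 5 (adjusted p = 0.949). Cd74, which B cells and antigen-presenting cells express, rose from 4.08 ± 0.766 to 24.8 ± 3.45 CPM (2.58, SE 0.22, adjusted p = 0.000456 by edgeR).

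In all, 1915 genes were higher and 1848 lower with CoA by edgeR, and 3724 of the 3763 moved the same way in all 3 mice. Without the mouse block the counts were 800 and 662. They were 756 and 569 without the Tc0 library with CoA of mouse 725, 815 and 670 without that of mouse 728, and 656 and 504 without the Tc0 library of mouse 725.

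The direct comparison of Tc22 cells with Tc0 cells given CoA asks where these populations differ from each other. Of the cytokine genes, Il22 (-2.31, SE 0.30, adjusted p = 0.000959 by edgeR), Il17a (-3.46, SE 0.31, adjusted p = 0.000217), Ifng (-3.84, SE 0.42, adjusted p = 0.000461) and Il2 (-4.18, SE 0.49, adjusted p = 0.000630) were lower in Tc22 cells. Gzmb (-1.02, SE 0.12, adjusted p = 0.000733), Ahr (-1.84, SE 0.16, adjusted p = 0.000224) and Slc5a6 (-0.96, SE 0.18, adjusted p = 0.00463) were lower too. Among the largest differences, Ccl3 (-5.06, SE 0.37, adjusted p = 0.000126) and Penk (-4.23, SE 0.30, adjusted p = 0.000126) were lower in Tc22 cells, and Cd7 (5.94, SE 0.52, adjusted p = 0.000203) and Fam183b (3.54, SE 0.31, adjusted p = 0.000217) higher.

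Against Tc0 cells with CoA, the cytotoxic list was lower in Tc22 cells: 1 of 25 measured members were higher and 16 lower (3 and 16 adjusted over the list alone). It had a camera adjusted p of 2.77e-11 (adjusted p = 0.0440 with an estimated correlation), the one list call in any comparison that held with an estimated correlation. Of the ribosome biogenesis genes, 0 of 25 measured members were higher and 25 lower (0 and 25 adjusted over the list alone), with a camera adjusted p of 2.00e-14 (adjusted p = 0.288 with an estimated correlation). Of the mitochondrially encoded respiratory genes, 0 of 13 measured members were higher and 12 lower (0 and 12 adjusted over the list alone), with a camera adjusted p of 8.01e-10 (adjusted p = 0.288 with an estimated correlation). Of the hypoxia response genes, 22 of 23 measured members were higher and 1 lower (22 and 1 adjusted over the list alone), with a camera adjusted p of 3.87e-11 (adjusted p = 0.288 with an estimated correlation). Of the glycolytic genes, 16 of 22 measured members were higher and 2 lower (16 and 3 adjusted over the list alone), with a camera adjusted p of 7.09e-05 (adjusted p = 0.463 with an estimated correlation). Of the aryl hydrocarbon receptor targets, 6 of 10 measured members were higher and 1 lower (6 and 1 adjusted over the list alone), with a camera adjusted p of 0.00102 (adjusted p = 0.231 with an estimated correlation).

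Other list differences in this comparison included the type 17 list, in which 2 of 18 measured members were higher and 9 lower (2 and 9 adjusted over the list alone). It had a camera adjusted p of 0.00289 (adjusted p = 0.419 with an estimated correlation). In the type 2 cytokine list, 1 of 10 measured members were higher and 5 lower (1 and 5 adjusted over the list alone), with a camera adjusted p of 0.00109 (adjusted p = 0.231 with an estimated correlation). In the integrated stress response and serine synthesis list, 4 of 23 measured members were higher and 11 lower (4 and 11 adjusted over the list alone), with a camera adjusted p of 0.0208 (adjusted p = 0.576 with an estimated correlation). This call was lost without the Tc0 library with CoA or the Tc22 library of mouse 728 (adjusted p from 0.0939 to 0.196). In the oxidative stress list, 7 of 18 measured members were higher and 0 lower (7 and 0 adjusted over the list alone), with a camera adjusted p of 0.00109 (adjusted p = 0.231 with an estimated correlation). In the tissue residency list, 6 of 13 measured members were higher and 2 lower (7 and 2 adjusted over the list alone), with a camera adjusted p of 0.0148 (adjusted p = 0.288 with an estimated correlation). In the fatty acid synthesis list, 8 of 18 measured members were higher and 1 lower (8 and 1 adjusted over the list alone), with a camera adjusted p of 0.0270 (adjusted p = 0.417 with an estimated correlation). The last call was lost without the Tc0 library with CoA of mouse 715 (adjusted p = 0.0810).

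Dendritic cell markers were lower in Tc22 cells than in Tc0 cells with CoA: 0 of 6 measured members were higher and 3 lower (0 and 3 adjusted over the list alone). They had a camera adjusted p of 0.0171 (adjusted p = 0.417 with an estimated correlation), and the call was lost without the block (adjusted p = 0.0715) and without the low-count filter (0.132). Of the granulocyte and mast cell markers, 0 of 3 measured members were higher and 3 lower (0 and 3 adjusted over the list alone), with a camera adjusted p of 0.00564 (adjusted p = 0.231 with an estimated correlation). The coenzyme A list had 0 higher and 4 lower of 17 (adjusted p = 0.254) and did not pass by camera. In all, 2456 genes were higher and 2457 lower in Tc22 cells by edgeR, and 4891 of the 4913 moved the same way in all 3 mice. Without the mouse block the counts were 1017 and 1080. They were 1244 and 1190 without the Tc0 library with CoA of mouse 725, 1274 and 1182 without that of mouse 728 and 1148 and 1037 without the Tc22 library of mouse 725, and 1588 genes were lower without the Tc22 library of mouse 715.

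The changes against Tc0 were also set side by side. Of the genes past the threshold in both comparisons, 136 were higher in both, Il22, Il1r1, Il23r and Gzmc among them, and 55 were lower in both. Independent lists of these sizes would share 47.4 and 22.3 genes. In simulated counts with no effect, where both comparisons shared simulated Tc0 libraries, 0.2 and 0.1 genes were shared on average. With no effect few genes can be called at all. These simulated counts thus cannot tell how many of the shared genes come from the shared controls. In opposite directions, 41 genes were higher in Tc22 and lower with CoA (independent lists 45.8, simulated 0) and 26 were lower in Tc22 and higher with CoA (23.1 and 0). Across genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.252, against 0.502 simulated with no effect. Their covariance was 0.0983 against 0.0449 simulated, a difference of 0.0533. With 3 Tc0 libraries the controls could not be split into groups of at least 2, so part of the excess may come from the shared controls. The 191 genes in the same direction became 45 without the mouse block and 396 without the low-count filter. They became 991 without the Tc0 library of mouse 728, 53 without that of mouse 725, 111 without the Tc0 library with CoA of mouse 728, and 92 and 97 without the Tc22 libraries of mice 715 and 725. The correlation was 0.440 and 0.452 without the Tc0 libraries of mice 715 and 728.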

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

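All alternatives were fixed in advance. No gene called in a comparison changed sign under any of them. The scalings (DESeq2's size factors, library size alone, upper quartile) kept every count of genes and lists within 1.5 times, as did the filter of 1 CPM in 3 libraries. A fit of the compared groups alone kept the counts of genes higher and lower within 1.5 times; its lists were not tested. Whole counts left no unrounded values to test.

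Without the mouse block, edgeR called 87 genes higher and 33 lower for Tc22 against Tc0, 800 and 662 for Tc0 with CoA against Tc0, and 1017 and 1080 for Tc22 against Tc0 with CoA, and 45 genes in the same direction in both comparisons with Tc0; every one of the calls without the block was also made with it. Without the low-count filter Tc22 against Tc0 had 831 genes higher and 444 lower, the shared genes numbered 396 and the correlation of fold changes was 0.403. DESeq2 called 621 and 332 for Tc22 against Tc0. A minimum 2-fold change left 239 and 89, 637 and 581, and 953 and 691 genes in the comparisons in the order above, by construction. With an estimated correlation 0, 0 and 1 lists passed. The causes of the other shifts were not tested.

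Leaving out a library or a mouse gave 148 to 1555 genes higher and 53 to 1114 lower for Tc22 against Tc0 (7 to 15 lists), 468 to 2360 and 342 to 1996 for Tc0 with CoA against Tc0 (11 to 17 lists), and 980 to 2935 and 868 to 2978 for Tc22 against Tc0 with CoA (13 to 19 lists). The genes in the same direction in both comparisons with Tc0 ranged from 53 to 991 and the correlation from 0.219 to 0.452. The highest counts of Tc22 against Tc0 came without the Tc0 library of mouse 728, the lowest without the Tc0 or the Tc22 library of mouse 725; those of the other comparisons fell most without mouse 725.

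Of the genes past the threshold that the naming rule takes, whether or not the text names them, 36 of 61 stayed past it without each library for Tc22 against Tc0, 79 of 126 for Tc0 with CoA against Tc0 and 16 of 18 for Tc22 against Tc0 with CoA; without the block 26, 77 and 16 did. Of the lists, 8 of 12, 9 of 13 and 12 of 14 did so without each library, and 9, 11 and 13 without the block. Where an arm keeps 2 libraries, the shared estimate of spread from all groups carries the test. Of changes of 1.5-fold, 26.2% and 25.8% were recovered in simulated counts for the comparisons with Tc0. Few genes were changed in those counts, so these shares need not hold for the real data. Recovery by expression level was not tested.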

Other observations

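The tests chosen only after the results were seen are the 3 gene lists of the next paragraph and the tests of exchanged labels, of RNA from dendritic cells, of RNA from basophils or mast cells, of a lower share of T cells, of the scaling and of culture conditions; those of depth, of abundant genes, of GC content and length and of other splits were written down beforehand.

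Lists of interferon-inducible GTPases, NF-kB pathway genes and cytosolic aminoacyl-tRNA synthetases were put together after their genes were seen to move, and both comparisons with Tc0 share the same Tc0 libraries, so they are not independent. The 17 GTPase genes, which include Iigp1 and Tgtp2 and share reads, had a median log2 fold change of -0.88 in Tc22 against Tc0 (camera adjusted p = 8.74e-20, and adjusted p = 0.228 with an estimated correlation; adjusted over 9 tests) and -0.68 with CoA (camera adjusted p = 1.75e-06, and adjusted p = 0.388 with an estimated correlation). The 17 NF-kB pathway genes had medians of 0.68 (camera adjusted p = 8.79e-15, and adjusted p = 0.135 with an estimated correlation) and 0.55 (camera adjusted p = 2.19e-05, and adjusted p = 0.276 with an estimated correlation). The 18 synthetase genes had a median of 0.53 with CoA (camera adjusted p = 3.98e-06, and adjusted p = 0.356 with an estimated correlation) and -0.37 in Tc22 against Tc0 with CoA (camera adjusted p = 0.00244, and adjusted p = 0.474 with an estimated correlation). With the preset correlation these calls held without each library in turn, with adjusted p up to 0.00124 against Tc0 and up to 0.0317 in the direct comparison, and without the block. The genes were picked from these same libraries. Neither the p-values nor the leave-outs are therefore separate support for the lists. In Tc22 against Tc0 with CoA the GTPase list did not pass (camera adjusted p = 0.0888), but it did without the Tc0 library with CoA of mouse 725 (0.00363), the Tc0 library of mouse 715 (0.00104) or 725 (0.0418) or the Tc22 library of mouse 715 (0.0176). The NF-kB list did not pass there (0.186) except without the Tc0 library with CoA of mouse 725 (0.0393). The synthetase list did not pass in Tc22 against Tc0 (0.109) except without the Tc0 library of mouse 715 (0.0170) or the Tc22 library of mouse 728 (0.0381).

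The Tc0 library of mouse 728 lay apart from the other Tc0 libraries. Exchanged labels between the Tc0 and Tc22 libraries of that mouse are argued against: the mean log2 CPM of the aryl hydrocarbon receptor target list in the Tc0 library lay -1.04 from the lowest of the other Tc22 libraries, and its Tc22 library, at 1.81, lay above the other Tc0 libraries, at 0.635 and 0.642. Greater depth and a few abundant genes are argued against as whole causes: thinned to 1 depth, the library's smaller chi-square per degree of freedom against another Tc0 library was 112, against at most 63.5 for the other pairs, and without the 100 most abundant genes it was 80.6 against 53.0. A difference of this mouse or its cultures stays open. The library's deviations correlated with those of the same mouse's CoA and Tc22 libraries (r 0.617 and 0.538 across genes). The Tc0 library of mouse 715 correlated with that mouse's CoA and Tc22 libraries with r of 0.305 and 0.597. Deviations cancel out over the libraries of a group. A departure of mouse 728 in every group could thus give such correlation in the other mice too. These values therefore cannot tell whether the correlation is particular to mouse 728.

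Markers of dendritic cells and of granulocytes and mast cells were higher in Tc0 cells with CoA by camera with the preset correlation. Neither list passed camera with an estimated correlation (adjusted p = 0.454 and 0.277). A lower share of T cells stays open, since the values go both ways. In mean log2 fold change over 3 mice the dendritic list exceeded the natural killer cell list by 1.40 (SE 0.403). Most natural killer cell markers lay near 1 CPM or below in Tc0. The dendritic list exceeded the macrophage list by 0.39 (SE 0.187), more than the SE, and the B cell list by 0.38 (SE 0.406), less than the SE. The granulocyte and mast cell list rose by 2.37 (SE 0.155) and the B cell list by 0.91 (SE 0.183), but the former summed to only 0.730 CPM in Tc0. CD8 T cell markers were lower (-0.28, SE 0.137). Summed B cell markers stood at 219 ± 38.8 CPM with CoA and 309.2 ± 141.7 CPM without (SD, n = 3). RNA from dendritic cells stays open too: of 7 abundant transcripts of antigen-presenting cells, 3 rose (Cd74 2.58, H2-Eb1 1.03, H2-Aa 0.92) and 1 fell (H2-Ab1 -0.96), with a median of 0.26, and Cd74, H2-Aa and H2-Ab1 are also in the B cell list. H2-Aa was lost without the Tc0 library with CoA of mouse 725 or the Tc0 libraries of mice 715 or 725 (adjusted p from 0.0553 to 0.101), and H2-Ab1 without the Tc0 library of mouse 725 (0.0536); without the block they stood at 0.0667 and 0.240. RNA from basophils or mast cells stays open, since the counts are too few to decide: of 5 transcripts outside the list's measured members, at no more than 27 counts in a library, 12 of 15 pairs of a transcript and a mouse were higher with CoA.

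Hypoxia response genes were lower and ribosome biogenesis genes higher with CoA. GC content and transcript length as whole causes are argued against: with both trends removed the list medians were -0.63 and 0.82 (camera adjusted p = 8.70e-05 and 5.35e-16; 0.566 and 0.503 with an estimated correlation, at which neither passed before removal either, 0.493 and 0.454) while the calls over all genes moved to 2696 higher and 2507 lower. The scaling as the whole cause is argued against, since 1 factor per library shifts both lists alike while the ribosome biogenesis list exceeded the hypoxia list by 1.48 on the log2 scale (SE 0.517, n = 3 mice; 0.80 and -0.67). A difference in conditions between culture wells, such as cell density, stays open, and the effect of CoA itself cannot be told apart from it here. The hypoxia list ranged over 0.99 on the log2 scale among the 3 Tc0 libraries, against a mean difference with CoA of -0.67 (SD 0.54, n = 3). That range spans different mice, so it holds differences between mice as well as between cultures and cannot decide the question. Within each mouse the hypoxia list was lower with CoA.

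Each comparison of 3 libraries with 3 has 10 splits, too few for a share under 0.05. The real split gave 565 genes past the threshold for Tc22 against Tc0, and the highest of the other splits 0 by edgeR, which had 83 to 2586 genes at an unadjusted p under 0.05 against 3248 in the real split. For Tc0 with CoA against Tc0 the values were 3763 and 0 (53 to 2055 unadjusted, against 5850), and for Tc22 against Tc0 with CoA 4913 and 1 (58 to 2268, against 6653). In each, 1 split of 10 was as large as the real one, the real one itself. Of the other splits, 3 part all 3 mice like the real one, and 6 part 1 mouse and keep both libraries of the others together.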
